A study of Arabidopsis thaliana with 2 samples.

How the data were processed

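The series measured messenger RNA in leaves of Arabidopsis thaliana accession Col-0, 24 h after the leaves were injected by syringe. The mock sample received 5 mM MgSO4 alone. The infected sample received Pseudomonas syringae pv. maculicola ES4326 (Psm ES4326), a bacterial leaf pathogen, suspended in the same solution. Each group had 1 sample and 1 array, so no difference has a replicate check and no p-value is given. Both arrays carry the label set C. The inoculum is written in the labels as 10E5 colony-forming units per square centimetre, a notation that leaves the exponent open. The sample labels give an age of 33 days after planting, whereas the description of the series gives 3 to 4 weeks. Total RNA was extracted with Trizol and labelled with the Affymetrix One-Cycle kit, per the labels' protocols.

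The deposited table holds 22810 probe sets in 2 columns, 1 per sample. Its values were taken as log2 expression because the deposited values run from 2.34 to 13.97, above the natural log or log10 of a 16-bit scanner's ceiling. The method that summarised probes into probe sets, the background correction, the scaling and the software are not given in the sources used here. No other sample's column was present. An array gives no read depth, and the number of arrays limits the precision.

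A rule set before the data were examined used the deposited values directly if the 2% trimmed means of the linear values, or all quantiles, lay within 1% of each other. The trimmed means were 141 and 146, apart by 3.61%, and the quantiles differed by up to 18.1%, so the arrays were quantile normalized. Values below each array's 40th percentile of plant probe sets were then set to that percentile, a log2 value of 4.18 on both arrays. A gene at this floor on both arrays received no call. A gene at the floor on 1 array has a lower bound, written as at least N-fold. A gene was called higher or lower at 2-fold, a rule of size and not a test.

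Probe sets were named through the platform annotation, with symbols updated by gene identifier through a RefSeq gene table of assembly TAIR10.1, which was used for names only. Of 22746 plant probe sets, 13513 named 1 gene, 503 named several and 8730 were not listed, and the last 2 kinds stayed unnamed. Of the 13513, 13436 matched the RefSeq table and 77 kept the annotation's own name. They stood for 13356 genes. Where a gene had several probe sets, as 146 did, the one with the highest mean was used.

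Before the data were examined, 27 gene lists were fixed by locus and 2 by rule. Only 61 of the 446 listed loci had a named probe set, so most lists were read from a few members. The cytosolic ribosomal protein rule matched 0 genes. The chloroplast list was to take loci starting with ATCG, but the gene table uses other tags, so genes placed on the plastid chromosome were taken instead. A list's median was computed over members above the floor on at least 1 array, and only with at least 3 such members, a minimum set after the coverage was known and before any ratio was computed. Its interval is a 95% binomial interval over the members, or their full range where they are too few, and it describes spread between genes only. Each median was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. The members of these lists were drawn independently, so genes that move together are not allowed for. A percentile therefore describes these arrays and is not a p-value.

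The named genes follow a rule fixed in advance. It takes the 12 highest and the 12 lowest log2 ratios among genes measured on both arrays, the 5 largest bounds in each direction, up to 4 members of each fixed list with the largest absolute ratio, and 9 defence marker genes whatever their values. Of those 9, only PDF1.2 had a named probe set. The rule gave 87 genes. A further 34 gene families, used mostly in the closing section, were defined by symbol after the annotation was seen and before ratios were computed. By then the values of some control probe sets, and of the first few probe sets of the table, some of them mitochondrial, had been seen.

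The alternatives were median centring, the values as deposited, loess, no floor, floors at the 20th and 60th percentiles, log2(value + 16), thresholds of 1.5-fold and 3-fold, and the mean of a gene's probe sets. Leaving out probe sets that can bind several transcripts, and centring on the poly(A) spike-ins, were added after seeing the data. The steps were tested on simulated data for the comparison of infected with mock, over 13356 genes, with noise of SD 0.20 in log2 units taken from the spike-ins in the deposited values. At a simulated log2 ratio of 1.5, 50 of 50 genes were called, at -1.5, 49 of 50, and at 3 and -3, 50 of 50 each. Of 7256 unchanged genes, 0 were called, which noise this small against a 2-fold cut largely sets in advance. The simulation changed 200 genes, all well above the floor before the change, far fewer than differed between the real arrays. Calls of dimmer genes were not tested. This noise leaves out differences between plants. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.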

Results

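Gene expression was measured on 1 array from mock-injected leaves and 1 array from leaves injected with Psm ES4326, both harvested at 24 h. The comparison asks how leaf transcripts differ once this pathogen has been in the tissue for a day. Ratios are infected over mock throughout, on the log2 scale unless a fold is given. Without replicates, no difference could be set against the variation between plants.

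Measured genes of photosynthesis, the Calvin cycle, photorespiration and chlorophyll synthesis were mostly lower in infected leaves. The 3 measured genes of the oxidative stress and glutathione transferase list, out of 28 fixed members, were higher, as were single genes of hormone metabolism. Only GSTU25 of these 3 is a transferase. The glutathione transferase family formed by symbol had 1 of 9 measured genes higher and 3 lower. All 13 measured nuclear genes of the photosynthetic light reactions, the Calvin cycle and photorespiration were at least 2-fold lower. UGT76B1, a glucosyltransferase of salicylic acid and related defence compounds, was at least 179-fold higher, and GH3.3, which joins auxin to amino acids, was 119-fold higher. Of 7936 genes above the floor on at least 1 array, 1550 (19.5%) were at least 2-fold higher and 1719 (21.7%) at least 2-fold lower.

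The calls included 263 higher and 253 lower genes that were at the floor on 1 array. At least 4-fold differences were seen for 601 higher and 703 lower genes, and at least 8-fold differences for 264 and 255. The log2 ratios had a median of 0.02 and an SD of 1.51 over genes, which describes these arrays and is not an error. The 42 bacterial and phage spike-in probe sets, which carry no plant RNA, had a median ratio of 0.03 and an SD of 0.27, and none reached 2-fold. In the deposited values, before quantile normalization, their SD was 0.20. Their ratios varied with signal level. All poly(A) spike-in probe sets with a mock log2 value of up to 6.54 had positive ratios, up to 0.51. BioDn-3, at a mock value of 10.19, had -0.58, while the brighter cre probe sets had positive ratios.

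**Figure D1:**
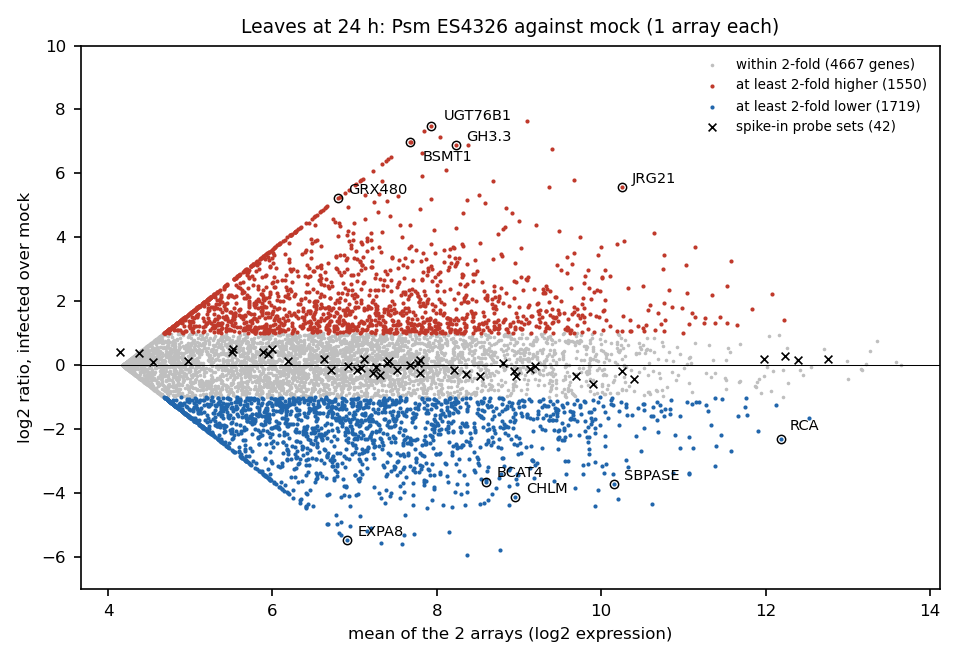
Log2 ratio of infected over mock against the mean log2 expression of the 2 arrays, 1 point per gene above the floor on at least 1 array, with spike-in probe sets as crosses. The 1550 genes at least 2-fold higher are red, the 1719 at least 2-fold lower are blue, and the straight diagonal edges are genes at the floor on 1 array, whose ratios are bounds.

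Among genes with a named probe set and measured on both arrays, the largest ratio belonged to AT1G68620, a carboxylesterase, at 7.62. It went from a log2 value of 5.28 to 12.91. AT5G38710, a proline dehydrogenase, followed at 7.13, or 140-fold. The ranking leaves out the 6469 unlisted plant probe sets above the floor and the 306 that name several genes, so it need not hold the array's extremes. The jasmonate oxidases AT2G38240 and JRG21, which inactivate the hormone, had ratios of 6.77 and 5.58, and JRG21 was already at 7.46 in mock leaves. GH3.3 and AT3G13950 both had a ratio of 6.89. AT4G39670, a glycolipid transfer protein, had 6.12, and AT3G47540, of the chitinase family, 5.79. The others of the 12 highest were AT2G37750 at 6.64, AT5G38900 at 5.90, AT3G18250 at 5.77 and AT1G33950 at 5.75. Among genes at the floor in mock leaves, AT3G13610, the hydroxylase of scopoletin synthesis, was at least 161-fold higher. AT4G23680 was at least 128-fold higher, BSMT1, which makes methyl salicylate, at least 127-fold, and AT1G30700, of the berberine bridge enzyme family, at least 91.4-fold.

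Among genes with a named probe set and measured on both arrays, the lowest ratio was -5.94, for AT1G29660. This GDSL-type lipase gene went from 11.33 to 5.39. Further GDSL-type genes, AT3G16370 and AT1G29670, had ratios of -5.79 and -5.56. The acid phosphatase-type genes AT1G04040 and AT5G44020 had -5.60 and -5.26. AT5G63180, of the pectate lyase type, had -5.08, and AT5G62350, of the invertase and pectin methylesterase inhibitor type, -4.89. The remaining genes of the 12 lowest were AT5G16030 at -5.30, AT2G10940 at -5.23, AT3G15310 at -5.18, AT4G21870 at -5.04 and AT5G44680 at -4.97. At the floor in infected leaves, EXPA8, a wall-loosening expansin, was at least 43.9-fold lower and AT5G48490, a lipid transfer protein, at least 38.2-fold. AT1G49200 was at least 39.2-fold lower, AT1G15260 at least 31.5-fold and AT5G55220 at least 31.2-fold.

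In the photosynthetic light reactions, 7 of 7 measured genes were at least 2-fold lower, with a median of -2.59 (members' range -3.40 to -1.44), at percentile 0.02 of random lists. LHCB4.2, of the photosystem II antenna, had a ratio of -3.40. PSAN, of photosystem I, had -2.68, ATPC1, of the ATP synthase, -2.60, and PSBY, of photosystem II, -2.59. All 3 Calvin cycle genes were lower, with a median of -3.38 at percentile 0.21. SBPASE had -3.71, PRK -3.38 and RCA, the rubisco activase, -2.30 from a mock value of 13.34. Of photorespiration, 3 of 3 genes were lower, with a median of -3.38 at percentile 0.075. The glycine decarboxylase subunit AT1G11860 had -3.92, the hydroxypyruvate reductase HPR -3.38 and the glycerate kinase AT1G80380 -1.21.

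Chlorophyll synthesis had 3 of 4 genes at least 2-fold lower and a median of -3.04, at percentile 0.05. The magnesium protoporphyrin methyltransferase CHLM had -4.13, the magnesium chelatase subunit CHLI2 -3.66 and PORB -2.43, whereas GSA1, of an early step, had -0.58. With the floor at the 60th percentile this median was -1.97.

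Among 68 measured genes of the plastid genome, 32 were at least 2-fold lower and 0 were higher. Their median of -0.91 (95% interval -1.23 to -0.70) lay at percentile 0.01. The lowest were rps16 at -3.03, rps18 at -2.24, rbcL, the large subunit of rubisco, at -2.19 and psbN at -2.09. Of the plastid ribosomal protein genes 12 of 15 were at least 2-fold lower, with a median of -1.42, and of the plastid photosystem genes 8 of 20, with a median of -0.43 at percentile 15.0, inside the middle 95% of random lists. The difference between these groups, formed by symbol after the annotation was seen, was not tested and goes with signal level: 7 photosystem genes and 1 ribosomal gene had mock log2 values of at least 12, and below 12 the medians were -1.14 (95% interval -1.73 to -0.40) and -1.43 (-2.09 to -1.07). Plastid transcripts carry few poly(A) tails and are read less directly by this labelling. The 3′ minus 5′ signal, a measure of RNA integrity, was 1.47 in mock and 1.35 in infected leaves for actin. It was -0.45 and -0.25 for GAPDH, and 0.17 and 0.29 for ubiquitin.

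**Figure D2:**
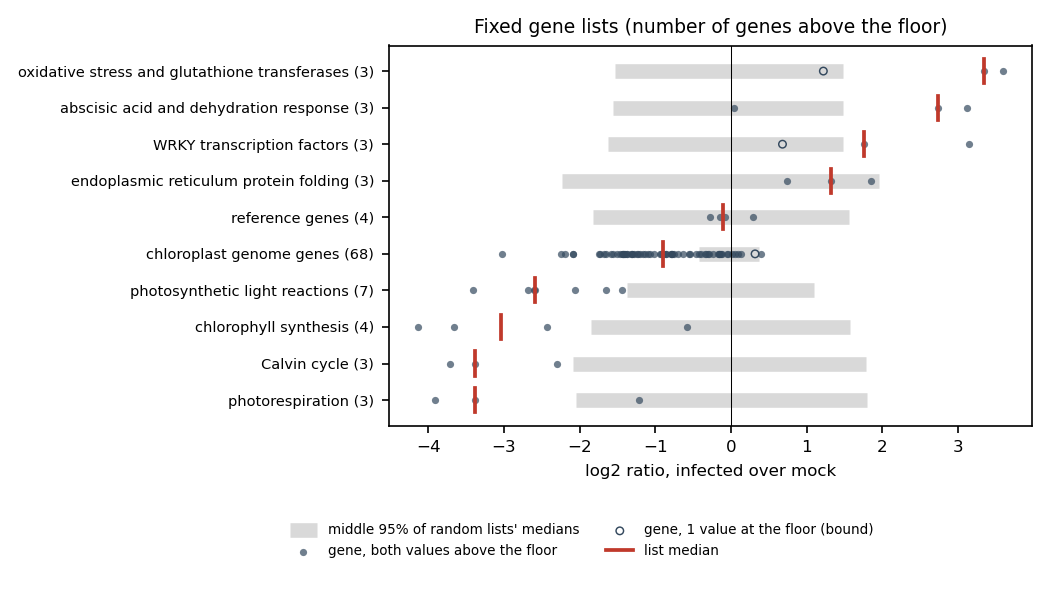
Log2 ratio of infected over mock for each measured gene of the 10 fixed lists with at least 3 genes above the floor, filled for genes measured on both arrays and open for bounds. Red ticks are list medians and grey bars the middle 95% of medians of 10000 random lists; the photosynthesis, Calvin cycle, photorespiration, chlorophyll and plastid medians lie below their bars.

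Several stress lists lay on the other side of 0, each read from 3 genes. In the list of oxidative stress and glutathione transferases 3 of 3 measured genes, out of 28 fixed members, were at least 2-fold higher. Their median was 3.35, at percentile 99.8. The glutathione transferase family formed by symbol had 1 of 9 measured genes higher and 3 lower. The zinc finger factor STZ had 3.59, AT2G21640, a marker of oxidative stress, 3.35, and GSTU25, a glutathione transferase, was at least 2.33-fold higher. Of the abscisic acid and dehydration list 2 of 3 measured genes, out of 22 fixed members, were higher, with a median of 2.73 at percentile 99.7. All 3 are COR genes, and no gene of abscisic acid synthesis or signalling was among them. COR15A had 3.12 and COR47 2.73, while COR15B had 0.04. Of the WRKY transcription factors 2 of 3 were higher, with a median of 1.76 at percentile 98.3. WRKY6 had 3.15 and WRKY53 1.76, while WRKY22 had a bound of 0.68. For protein folding in the endoplasmic reticulum, 2 of 3 genes were higher, with a median of 1.33 at percentile 91.9, inside the middle 95% of random lists. ATERDJ3B had 1.85, BZIP60, a factor of the unfolded protein response, 1.33, and CRT1b 0.74.

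The other lists, apart from the reference genes, had fewer than 3 measured genes and only single genes can be given. For salicylic acid, the glutaredoxin GRX480 was at least 37.3-fold higher and SAG101, a partner of EDS1, had a ratio of 2.23. For tryptophan synthesis, AT2G04400, the indole-3-glycerol phosphate synthase, had 2.98. In the jasmonate list BSMT1 was higher, as given above, and the defensin PDF1.2 went from 5.12 to the floor, a bound of -0.94. Among receptor kinases and their partners, BIK1 had 1.13 and EFR a bound of 0.82. Of the auxin list, WES1, a relative of GH3.3, went from 5.51 in mock to 7.51 in infected leaves. The sugar transporter SWEET4 had 3.93, and APL3 a bound of 0.63. CCR2, of lignin synthesis, was at least 2.02-fold higher, UF3GT, of anthocyanin synthesis, had 0.45, and SAG29, of senescence, a bound of 0.68.

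On the lower side, both measured genes of aliphatic glucosinolate synthesis were at least 2-fold lower, BCAT4 at -3.64 and the glucosyltransferase AT2G31790 at -2.92. EXPA4 was, like EXPA8, at the floor in infected leaves, at least 9.54-fold lower. The expansin family formed by symbol had 2 of 10 measured genes lower, 0 higher and 8 within 2-fold. The guard cell markers parted, with AT1G22690 at -4.07 and FMA at -0.33. The heat shock genes HSA32 and AT1G53540 had -0.09 and a bound of 0.04. The clock list's 1 named gene was at the floor on both arrays, and the ethylene, epidermis, phloem, xylem and cytosolic ribosomal lists had 0 named genes. All 4 reference genes lay within 2-fold, with a median of -0.11 that turned to 0.01 under median centring. They were AT2G28390 at 0.29, PEX4 at -0.27, AT4G26410 at -0.14 and AT4G34270 at -0.08.

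Calls of PDF1.2, CCR2, EFR and SAG29 at 2-fold depended on the processing. Most lists rest on a small part of their fixed members, so they describe the genes named and not the pathways as a whole.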

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

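All tests of explanations in this part were chosen after the results had been seen. Among plant probe sets that the annotation does not list, and that no comparison above used, 1461 of 6469 above the floor (22.6%) were at least 2-fold higher in infected leaves and 1547 (23.9%) at least 2-fold lower. They drew attention as a signal outside the named genes, and they can be given only as counts. The 5 ubiquitin control probe sets, which the comparisons left out, had a median log2 ratio of 0.87 (0.73 to 0.90), against -0.24 for 6 actin and 0.37 for 5 GAPDH probe sets.

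Of all measured genes, 41.2% were at least 2-fold apart. Noise of hybridisation and scanning would move all 42 spike-in probe sets, and noise of labelling only the 24 of the poly(A) spike-ins. The largest absolute log2 ratio was 0.58 among the 42 and 0.51 among the 24, against an SD of 1.51 over genes. Another difference between these leaf collections or arrays cannot be told apart from the bacteria with 1 array per group. An effect of the infection remains open beside it, untested.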

How the results depend on the processing

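No paired analysis was possible because each group had 1 array. The counts of 1550 higher and 1719 lower genes stayed within 1.5 times under every scaling and floor run, from 1085 to 1640 higher and from 1188 to 1852 lower. At 3-fold they were 873 and 1019, and at 1.5-fold 2345 and 2423, which the thresholds themselves bring about. A floor at the 60th percentile kept 1085 of the 1550 and 1188 of the 1719. Over the 5 scalings, the share of calls that were higher ran from 43.8% with poly(A) spike-in centring, added after seeing the data, to 47.4% with quantile normalization. No scaling moved the median of all genes by 0.1. Quantile normalization, median centring and loess hold that median near 0 by construction, and it was -0.06 as deposited.

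The SD of log2 ratios, 1.51 as reported, was 1.5153 both with median centring and as deposited, 1.5188 with loess, 1.5176 without probe sets that can bind several transcripts (added after seeing the data), 1.2270 with no floor, 1.3601 and 1.4136 with floors at the 20th and 60th percentiles, and 1.0204 on log2(value + 16) with no floor, which changes both choices at once. The set of genes counted changes with the floor. With no floor all 13356 genes enter the SD, including the 5420 at the main floor on both arrays. How much each choice contributes was not tested.

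No list median past 2-fold changed sign under the alternatives that gave it a value. With the floor at the 60th percentile the abscisic acid, WRKY and oxidative stress lists had fewer than 3 genes left and no median. The intervals of lists with few members are their full range, so staying inside them is weak evidence of stability. The light reactions median ran from -2.66 to -2.51, the Calvin cycle from -3.45 to -3.32, the plastid genome from -0.98 to -0.82 and the oxidative stress list from 2.61 to 3.40. Of the 87 named genes, 4 crossed 2-fold under some alternative. PDF1.2 reached -1.28 with no floor, EFR 1.17 and SAG29 1.35, and CCR2 was 0.86 as deposited. Genes near the floor carry the least information, since 5420 genes were at it on both arrays.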

Other observations

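The families in this part were defined by gene symbol after the annotation was seen and before ratios were computed, except that a few mitochondrial values had been seen; all tests of explanations were chosen after the results. Of 34 families, 32 had a median, and 8 lay above and 5 below the middle 95% of their random lists. Autophagy genes were the steadiest of the higher families described here: 7 of 10 were at least 2-fold higher and 0 lower, with a median log2 ratio of 1.43 (95% interval 0.56 to 3.52) at percentile 99.6, and 1.32 to 1.54 over the alternatives. ATG8H had 4.28, ATG8B 3.52, APG8A 2.98 and ATG8D 2.01, all of the ATG8 group that decorates autophagosomes. Secretory and vacuolar sorting genes had 10 of 26 higher and 1 lower, with a median of 0.87 (0.70 to 0.95 over the alternatives). SEC1B had 3.22, VPS60.1 3.11, VPS20.1 3.04 and VPS9B a bound of -1.93. Of the calmodulin-like calcium sensors 4 of 7 were higher, with a median of 2.03 (1.03 to 2.56 over the alternatives). CML41 had 4.02, and CML37, CML38 and CML43 had bounds of 3.70, 3.44 and 2.03.

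The U-box ubiquitin ligases PUB19, PUB24, PUB23 and PUB43 had ratios of 3.91, 3.26, 2.88 and 2.73. Their family median of 2.73 went to 0.02 with no floor, where dim members enter it. The same holds for beta-glucosidases, at 1.72 and 0.08, subtilases, at 1.14 and 0.09, bZIP factors, at 1.22 and 0.01, and serine carboxypeptidase-like proteins, at -0.86 and -0.05. These 5 are among the families counted outside their random lists, so those counts rest in part on medians that depend on the floor, and the single genes are the safer reading. Of 10 measured beta-glucosidases 6 were at least 2-fold higher and 3 lower, BGLU45 and BGLU46 at bounds of 5.77 and 4.30 and BGLU16 at 2.75, against BGLU40 at -2.43, BGLU44 at -2.36 and BGLU33 at -1.33. Of 5 subtilases 3 were higher, SBT3.3 at a bound of 6.39, SBT3.5 at 4.93 and ATSBT5.2 at 1.14. Of UDP-glycosyltransferases 17 of 38 were higher and 7 lower, with UGT76E12 and UGT73D1 at bounds of 6.07 and 4.67. On the lower side, 7 of 9 IQ-domain proteins were at least 2-fold lower and 0 higher, with a median of -1.84 (-1.92 to -0.59 over the alternatives). IQD28 had -3.12, IQD22 -2.43, IQD24 -2.36 and iqd21 -2.05. Tubulins had 4 of 6 lower, with a median of -1.91 (-1.99 to -1.08 over the alternatives), TUB6 at -3.04 and TUA6 at -1.81. Glutathione transferases went both ways, with a median of 0.01 that turned to -0.07 as deposited and to -1.05 with the floor at the 60th percentile, and GSTU20 at -4.36 and GSTU18 at -3.86 stood against the higher GSTU25. The sugar transporters parted too, SWEET17 at -2.99, SWEET1 at -2.15 and SWEET11 at -1.60 against SWEET4 at 3.93.

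The organelle genomes leaned opposite ways, the mitochondrial one weakly. Of 14 measured mitochondrial genome genes 13 had ratios above 0, but 4 were at least 2-fold higher, among them cox2 at 1.77 and nad4L at 1.27, and 10 lay within 2-fold. Their median lay at percentile 97.2, inside the middle 95% of random lists, whose upper end was 0.57. Of 68 plastid genome genes 62 had ratios below 0.

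For these organelle genes, weaker capture of RNA with short or no tails would lower both. The mitochondrial median was 0.55 (95% interval over genes 0.29 to 1.14). If that rise is real, weaker capture alone would not give both directions. With 1 array per group and a median inside the middle 95% of random lists, the rise itself is not established. Weaker capture also cannot be excluded as a part of the plastid drop, because a larger rise of mitochondrial transcripts would hide it. None of the 5 scalings run turned either sign. The mitochondrial median was at lowest 0.41, with no interval end under 0.17, and no plastid interval end was above -0.66. These scalings differ little from one another, so a larger scaling error could still turn 1 sign. The gap between the 2 medians, 1.26 to 1.52 over the scalings, would stay under any constant shift. Median centring differs from the deposited values, and poly(A) centring from quantile normalization, only by such a shift, so their equal gaps carry no information. An error that varies with signal level, as the spike-in ratios did, could change the gap. With the floor at the 60th percentile the mitochondrial median was 0.29. A difference between the leaf collections other than the bacteria cannot be told apart with 1 array per group, and a shift of organelle transcripts with infection may be a hypothesis for replicated arrays.

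Nuclear photosynthesis, Calvin cycle and photorespiration genes were lower by more than plastid genome genes, with medians of -2.60 over 13 genes and -0.91 over 68. Probe sets filled by abundant plastid transcript could hide a difference, yet the 49 plastid genes with a mock log2 value under 12 had a median of -1.23 (95% interval -1.40 to -0.94), which leaves saturation short of the whole gap. The 19 plastid genes at 12 or above had -0.16, whereas 11 nuclear genes at such levels had -2.60. A constant shift between arrays leaves this difference as it is; a scaling trend with signal level could move it, but it was -1.76 as deposited and -1.69 after both quantile and loess normalization. Unequal priming of transcripts that carry few tails stays open and was not tested.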
